A study of Homo sapiens with 12 samples.

How the data were processed

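Total RNA of MiaPaCa-2 cells was hybridised to 12 single-colour Illumina bead arrays, 4 each of unsorted, triple negative and triple positive cells, and groups and replicate letters were taken from the sample labels. The deposited scanner table holds, per the file headers, the mean bead intensity of each probe on each array, the detection p-value of the probe against the array's negative controls, the standard error over its beads and the number of beads. Per the submitters' processing notes these were made in GenomeStudio, whose version is not given in the sources used here. The deposited intensity values are background-subtracted, as 12803 to 14187 probes per array lie at or below 0, and are not normalized between arrays. Another deposited table holds the authors' processed value of each probe on what the values show to be a log2 scale. Each of its columns ranked the probes as the scanner signals of its own array did (rank correlation 1.0000, at most 0.8843 with any other array). Its slope per doubling was 0.93 to 1.06 above a signal of 4000, it had the same distribution on every array with a median of 0, and it was flatter for dim probes, as after the addition of a constant of 79 to 113. The authors' normalization, constant and centring are not given in the sources used here.

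The scanner table has 47318 entries, of which 92 control entries stayed in for background correction and normalization and were left out afterwards. Gene symbols came from the file, and 35669 probes were matched by Entrez ID to current names in the reference gene table (assembly GRCh38.p14). Of the 13313 genes tested, 12243 had such a name and the others kept the file's. Signals were background-corrected with limma's nec function (normexp, offset 16), with the negative controls (770) inferred from the detection p-values, then quantile-normalized and brought to log2. Probes with a symbol and a detection p under 0.01 on at least 4 arrays were kept (17308). Another 600 probes that passed detection had no symbol and were left out. Each gene was represented by its probe with the highest mean. Of the tested genes 3201 had more than 1 probe, and probes of a gene were called in opposite directions for 109 genes in triple positive against triple negative cells, 157 in triple positive against unsorted and 29 in triple negative against unsorted cells. Probe coordinates are those of the file, which names no genome build, and were not converted. Probes detected per array ranged from 15113 to 16320 in unsorted, 15185 to 16177 in triple negative and 16162 to 16880 in triple positive arrays, and the 75th percentile of the signal from 32.7 to 54.5.

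A linear model of 3 group means was fitted to all 12 arrays with limma's lmFit and eBayes, and each comparison was adjusted by the Benjamini-Hochberg method over the 13313 genes, with a threshold of 0.05. The median standard error of a difference was 0.124 log2 units. Sizes are log2 differences on the offset scale, which understates changes of dim genes. A set of 33 gene lists was fixed before the data were examined: sort markers, stem cell factors, FOX family, epithelial, mesenchymal, sterol synthesis, fatty acid synthesis, hypoxia and glycolysis, mitosis, DNA replication, amino acid stress, ER chaperones, immediate early, YAP and cytoskeleton, matrix and integrins, proteases and invasion, Wnt, Notch, Hedgehog, interferon, inflammatory cytokines, oxidative stress, p53 targets, lysosome and autophagy, metallothionein, ribosomal proteins, histones, and markers of leukocytes, fibroblasts, endothelium, acinar, neuroendocrine and erythroid cells. The 29 lists with at least 3 tested genes were compared with all other genes by camera at its preset correlation of 0.01, adjusted over the 29 lists. Camera with the correlation estimated from the data was an alternative. Fry was run beside it and asks whether a list changed at all, without a comparison with other genes. Calls of lists in the text are those of camera, and fry p-values, not adjusted over the lists, are printed for a few lists only.

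The genes named in the text were also chosen by a rule fixed before the data were examined. They are the sort markers and FOXQ1; for each comparison the 10 genes with the largest rise and the 10 with the largest fall among those past the test, with no overlap between the arrays of the groups and with detection on all 4 arrays of the brighter group; and up to 4 genes with the smallest adjusted p from each list with 3 or more genes past the test. Provisional names were left out of this choice, 705, 763 and 302 of the genes called in triple positive against triple negative, triple positive against unsorted and triple negative against unsorted cells. Some genes chosen by this rule are not reported here, among them the gene of 1 of the 115 sets of arrays in the closing section, and all counts include them. Genes on the short arm of chromosome 9 named in the closing section were chosen otherwise, as stated there.

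The comparisons of triple positive cells with both other groups share the triple positive arrays. Their overlap was therefore set beside 50 simulations of groups without effects, beside independent lists of the same lengths, and beside all 6 splits of the triple positive arrays into 2 and 2. The letters a to d are not stated to mark a shared culture across groups. Deviations from the group means of arrays with the same letter correlated across genes at 0.16, 0.22, 0.24 and 0.51 (a to d) between triple positive and unsorted arrays, against 0.18 to 0.23 for different letters among a to c, at -0.01 to 0.08 between triple positive and triple negative and at -0.01 to 0.01 between triple negative and unsorted arrays. The rule that every pair must exceed 0.1 was met between the arrays of triple positive and unsorted cells and no others. It does not show a pairing by letter, as among a to c the same letters correlated about as different letters did. The shift shared by the d arrays also enters the deviations of a to c through the group means. A fit with the letter as a block was made for all 12 arrays and for those 8.

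Alternatives to the main processing were no background correction, a normexp offset of 50, scaling to the 75th percentile, cyclic loess, the authors' value table, other detection filters (none, p under 0.05 on at least 4 arrays, p under 0.01 on all 12 arrays), every detected probe in place of 1 per gene, a fit on the 8 arrays compared, array quality weights, the replicate block, and each array left out in turn. Leaving out the d arrays and the block on 8 arrays were added after the data were seen. The slide of an array was not used, as the files give none. The differential test was tested on simulated data, with 67, 67 and 66 of the 13313 genes shifted by 0.5, 1 and 2 log2 units on the real arrays' means and spreads. For triple positive against triple negative cells it recovered 56.7%, 89.6% and 100% of these and called 0.076% of unchanged genes. For triple positive against unsorted cells the shares were 50.7%, 89.6%, 98.5% and 0.061%. Triple negative against unsorted cells gave 61.2%, 88.1%, 100% and 0.061%. In the simulation genes varied independently, few were shifted and no array stood apart, unlike in the real data. These shares may therefore not hold for the real comparisons. Software was R 4.3.3 with limma 3.58.1 and data.table (1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the figures.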

Results

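MiaPaCa-2 is an established human pancreatic carcinoma cell line. Cultures of it were sorted by flow cytometry on 3 surface proteins, CD44, CD133 (the product of the PROM1 gene) and EpCAM, which are widely used together to select stem-like pancreatic cancer cells. Transcripts were measured on 12 Illumina bead arrays, 4 from unsorted cells, 4 from cells negative for all 3 proteins (triple negative) and 4 from cells positive for all 3 (triple positive), with the replicates of each group lettered a to d. The series design describes the 4 replicates as independently sorted cultures. Unsorted and triple negative cells were kept in medium with 5% fetal bovine serum and triple positive cells in serum-free sphere medium, so the sort and the medium of the triple positive cells changed together. Cells of another line in the triple positive arrays are a further candidate explanation of their differences, weighed in the closing section. Between 15113 and 16880 probes per array were detected above the negative control probes, with a median of 21 to 22 beads behind each signal, and 13313 genes entered the tests. P-values rest on the spread between arrays within groups, pooled over the 3 groups, and the number of arrays limits the precision. In bright probes, pairs of replicates without a d array differed by an SD of 0.108 to 0.136 log2 units. Bead standard errors alone give 0.082 to 0.108 there. The p-values may therefore understate the spread between separate cultures.

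The replicates of a group lay close together except for unsorted d and triple positive d. The median SD of a gene within a group was 0.186 log2 units in unsorted, 0.109 in triple negative and 0.164 in triple positive arrays, and 0.113, 0.099 and 0.101 without the d arrays. Cell cycle genes set these arrays apart. The mean of the 34 mitosis genes was 7.12 to 7.18 on unsorted a to c and 9.34 on unsorted d, and 7.23 to 7.26 on triple positive a to c and 8.85 on triple positive d. All triple negative arrays lay between 8.85 and 8.88. Triple positive d also differed from the mean of a to c of its group by -0.49 in the inflammatory cytokine list, -0.38 in matrix and integrins, -0.37 in amino acid stress, -0.33 in immediate early and -0.27 in p53 targets.

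In each fold given as "at least N-fold", the gene was not above background on any array of the dim group. The bright group's mean was set against the lowest detected signal on each array of the dim group (4.98 to 5.22 log2 units) or the probe's own signal where that was higher. The fitted log2 difference of such a gene is printed beside it and is not a bound. ALDH1A1, BMP4, BNIP3, CRIP1, CXCL5, HEYL, IFI27, SERPINA3 and SERPINE2 were above background on only some arrays of a dim group. Where they have a log2 difference and no bound, it is one from a level near background, which leaves its size and rank uncertain. For each list of genes fixed before the data were examined, the members past the test over all genes tested come first, followed by the number past it when p was adjusted over the list alone.

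The sort markers were compared as a check of the sort, and FOXQ1, a forkhead transcription factor, because the series title names it. EPCAM transcripts lay at 12.65 ± 0.05 log2 units (SD, n = 4) in triple positive cells and at 4.59 ± 0.15 in triple negative cells, where no array detected them, a difference of at least 184-fold (log2 difference 8.05, SE 0.11, adjusted p = 1.37e-15). PROM1 was likewise detected on the 4 triple positive arrays alone, at 8.25 ± 0.13 against 4.40 ± 0.07, at least 8.71-fold higher (log2 3.84, SE 0.08, adjusted p = 8.93e-14). The sort selects surface protein, which the arrays do not measure. CD44, the hyaluronan receptor, went against the sort in its transcripts. It was bright in every group and lower in triple positive cells, at 12.17 ± 0.13 against 12.96 ± 0.09 in triple negative and 13.03 ± 0.03 in unsorted cells (log2 -0.80 and -0.87, SE 0.09, adjusted p = 1.46e-06 and 6.40e-07). A dimmer CD44 probe, at 6.84 ± 0.27, 6.05 ± 0.08 and 6.06 ± 0.04 in unsorted, triple negative and triple positive cells, did not differ between the sorted groups (log2 0.01). A further CD44 probe was lower in triple positive than in triple negative cells (log2 -1.54). FOXQ1 rose to 11.51 ± 0.30 in triple positive cells from 5.87 ± 0.06 in triple negative cells (log2 5.64, SE 0.15, adjusted p = 7.35e-13) and from 5.36 ± 0.27 in unsorted cells (log2 6.15, SE 0.15, adjusted p = 2.96e-13). Its probe was detected on 2 of the 4 unsorted arrays and on all arrays of the sorted groups. The probe table places it on chromosome 6 at 1259749 to 1259798, on the plus strand, and names no genome build.

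**Figure D1:**
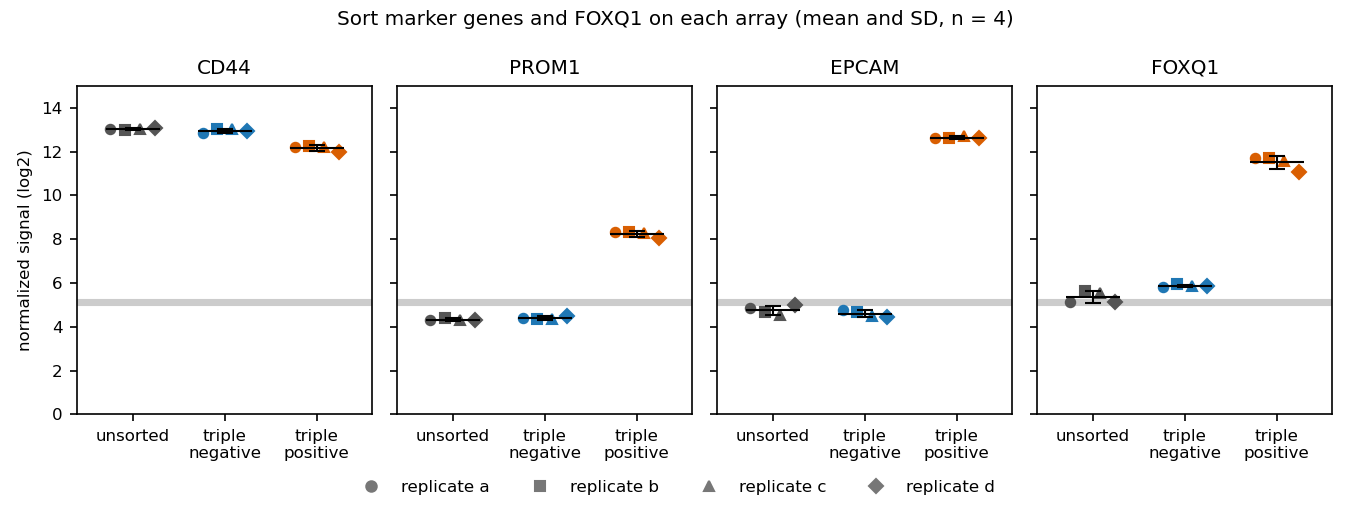
Normalized log2 signal of CD44, PROM1, EPCAM and FOXQ1 on each of the 12 arrays (points, shaped by replicate), with the mean and SD of each group (n = 4) and the range of the lowest detected signal per array (grey band, 4.98 to 5.22). EPCAM, PROM1 and FOXQ1 lie at 12.65, 8.25 and 11.51 in triple positive cells, above all 8 other arrays, and CD44 at 12.17 lies below them.

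Triple positive against triple negative cells asks how cells sorted as positive for all 3 surface proteins differ from cells sorted as negative. Epithelial genes and interferon-induced genes were higher in triple positive cells, where 21 of 23 measured epithelial genes and 22 of 28 interferon-induced genes rose, while the intermediate filament protein VIM fell by 7.46 and the fibrillar collagen COL5A2 at least 91.2-fold. The largest rises were those of IFI27, an interferon-induced gene (at least 251-fold), SERPINE2, a secreted inhibitor of serine proteases (at least 242-fold), and EPCAM. TM4SF1, a surface protein of the tetraspanin-like family, showed the largest fall, from 12.72 in triple negative cells to below background (at least 207-fold). Of the 13313 genes, 9239 (69.4%) changed, 4307 upward and 4932 downward, and 3659 changed at least 2-fold (1938 upward, 1721 downward). Neither majority held under every scaling, as cyclic loess gave 4813 upward and 4360 downward and 75th percentile scaling 1743 upward and 2031 downward at least 2-fold. A change of at least 16-fold was seen in 213 genes, 157 of them upward. On the dim side of the 2-fold differences, 790 of the genes that rose and 342 of those that fell were not above background on any array.

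The epithelial list rose as a group in triple positive cells, with 21 genes up, 1 down and 1 not past the test (22 adjusted over the list alone). Its median log2 difference was 2.55, or 2.22 with genes at their bound (camera adjusted p = 1.61e-10; adjusted p = 0.0539 with an estimated correlation). CDH1, the adherens junction protein E-cadherin, rose at least 25.1-fold (log2 5.46, SE 0.10), the tight junction protein CLDN7 at least 26.7-fold (log2 5.48, SE 0.08), and MAL2, a membrane protein of apical transport, at least 96.1-fold (log2 7.42, SE 0.09). SPINT2, an inhibitor of membrane serine proteases, was detected in all groups and rose by 4.31 (SE 0.08). Of 10 measured mesenchymal genes, 6 fell and 4 rose (10 adjusted over the list alone), and the list did not pass (adjusted p = 0.436). VIM fell by 7.46 (SE 0.17) from 14.03, COL5A2 at least 91.2-fold (log2 -7.13, SE 0.08) and TGFBI, a matrix protein induced by TGF-beta, at least 5.77-fold (log2 -3.00, SE 0.10).

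Stem cell factors passed the list test upward, with 9 of 14 measured genes up, 1 down and 4 not past (10 adjusted over the list alone; median log2 0.98, or 0.77 with genes at their bound, adjusted p = 0.0292; adjusted p = 0.342 with an estimated correlation and 0.0576 without background correction). The surface protein CD24 rose at least 17.2-fold (log2 4.42, SE 0.19), the polycomb protein BMI1 by 2.77 (SE 0.10) and the retinaldehyde dehydrogenase ALDH1A3 by 2.45 (SE 0.09). ALDH1A1, the related enzyme used as a stem cell marker, moved against the list and fell by 7.65 (SE 0.10), from 12.56 to 4.91, a level near background. Wnt pathway genes rose as well, 8 of 12, with 2 down and 2 not past (10 adjusted over the list alone; median log2 1.09, adjusted p = 0.034; adjusted p = 0.254 with an estimated correlation). AXIN2 and RNF43, feedback inhibitors induced by Wnt signals, rose at least 10.5-fold and at least 3.55-fold, the secreted Wnt inhibitor DKK1 rose by 5.01 (SE 0.15) to 13.34, and cyclin D1 (CCND1) by 2.23 (SE 0.11). The Wnt list did not pass after cyclic loess normalization (adjusted p = 0.0522), with a mean log2 difference of 1.38 against 1.32 in the main fit. Of the FOX family, 3 of 10 measured genes rose and 5 fell (8 adjusted over the list alone), with FOXC1 up by 1.62 (SE 0.16) and FOXK1 down by a log2 difference of -1.16 (SE 0.13). Notch genes were split, 4 up and 8 down of 15 (14 adjusted over the list alone). The Notch ligand JAG1 fell by 4.12 (SE 0.10) and the Notch target HEYL rose by 2.75 (SE 0.12).

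Of the 28 interferon-induced genes, 22 rose, 2 fell and 4 did not pass (24 adjusted over the list alone), with a median log2 difference of 1.58 (adjusted p = 1.51e-07; adjusted p = 0.342 with an estimated correlation). Besides IFI27, the transcription factor IRF7 rose at least 19.3-fold (log2 4.90, SE 0.11), IFI44 at least 13.9-fold (log2 4.40, SE 0.08), and IFI6 by 4.90 (SE 0.11) from 8.67 to 13.58. Immediate early genes were split, 8 up and 13 down of 24 (21 adjusted over the list alone). The phosphatases of the MAP kinase pathway DUSP4 (at least 16-fold), DUSP5 (log2 4.82, SE 0.17) and DUSP6 (at least 80.1-fold) rose, as did the early response gene IER3 (log2 5.23, SE 0.19). Among p53 targets 11 of 17 rose and 3 fell (14 adjusted over the list alone) without a call for the list (adjusted p = 0.146). The cell cycle inhibitor CDKN1A was the largest of these at 4.08 (SE 0.21). Inflammatory cytokine genes numbered 7 up and 4 down of 13 (11 adjusted over the list alone), among them the chemokine CCL2 at least 3.67-fold up.

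Mitosis genes were lower in triple positive cells, 21 of 34 down, none up and 13 not past (21 adjusted over the list alone). The median log2 difference was -1.27 (camera adjusted p = 0.0401, and 0.882 with an estimated correlation). That correlation was 0.968, and fry gave p = 0.0718. The kinesin KIF11 fell by 2.48 (SE 0.42), the centromere protein CENPF changed by -2.33 (SE 0.38) and the topoisomerase TOP2A fell by 2.51 (SE 0.45). Triple positive d stood apart here, with a list mean of 8.85 against 7.23 to 7.26 on a to c, and the mean difference from triple negative cells was -1.62 over the a to c arrays and -0.03 between the d arrays. The list lost its call without triple negative a (0.0512) or d (0.0526), and without triple positive a (0.103), b (0.0912) or c (0.0969), and also with 75th percentile scaling (0.113), without background correction (0.0576) and among genes detected on all 12 arrays (0.0864). The mean difference of the list was -1.38 to -1.08 in these, against -1.22. DNA replication genes numbered 5 up and 9 down of 34 (8 adjusted over the list alone), with a mean of 7.92 to 7.97 on triple positive a to c, 8.81 on triple positive d and 8.33 to 8.36 on triple negative arrays. GINS4, a part of the replicative helicase complex, fell by 2.51 (SE 0.30) and the polymerase POLA1 by 1.83 (SE 0.23).

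Lysosomal and autophagy genes fell, 17 of 22, with 2 up and 3 not past (19 adjusted over the list alone; median log2 -0.69, or -0.49 with genes at their bound, adjusted p = 0.0277; adjusted p = 0.878 with an estimated correlation). The lysosomal protease CTSD fell by 1.67 (SE 0.11) and the proton pump subunit ATP6V0D1 by 1.21 (SE 0.10). No other list passed. Metallothionein genes numbered 1 up and 7 down of 8 (8 adjusted over the list alone, adjusted p = 0.231), with MT1F at least 11.7-fold up and MT1M at least 6.71-fold down, and probes of the near-identical members of this family can share signal. Hypoxia and glycolysis genes were split, 7 up and 13 down of 30 (20 adjusted over the list alone). The mitochondrial protein BNIP3 rose by 4.86 (SE 0.10) and the aldolase ALDOC by 3.59 (SE 0.12), while the secreted glycoprotein STC1 fell at least 6.23-fold. Sterol synthesis genes numbered 7 up and 10 down of 24 (17 adjusted over the list alone) and fatty acid synthesis genes 4 up and 7 down of 14 (11 adjusted over the list alone). The elongase ELOVL6 rose by 3.73 (SE 0.13). Among ATF4 targets of amino acid stress, 17 rose and 11 fell of 38 (28 adjusted over the list alone), led by the transsulfuration enzyme CBS, at least 60.3-fold down, and the secreted protein STC2, at least 27.1-fold up. ER chaperone genes numbered 12 up and 3 down of 18 (15 adjusted over the list alone, adjusted p = 0.134), with HSP90B1 up by 0.97 (SE 0.09). NRF2 targets of oxidative stress numbered 7 up and 6 down of 17 (13 adjusted over the list alone), with the quinone reductase NQO1 down by a log2 difference of -2.25 (SE 0.09).

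Genes of the cell surroundings and the cytoskeleton went both ways. Matrix and integrin genes numbered 14 up and 8 down of 28 (23 adjusted over the list alone), with the laminin chain LAMB3 up at least 18.3-fold and the collagens COL17A1 and COL5A1 down (log2 -3.64, SE 0.09, and at least 6.14-fold). YAP and cytoskeleton genes numbered 11 up and 9 down of 24 (20 adjusted over the list alone), among them tissue factor F3 (at least 33.8-fold up) and the calponin CNN3 (at least 52.5-fold up). Protease and invasion genes numbered 6 up and 7 down of 15 (13 adjusted over the list alone), and the metalloprotease inhibitor TIMP1 fell by 1.88 (SE 0.09). Histone genes numbered 2 up and 6 down of 11 (9 adjusted over the list alone). Ribosomal protein genes numbered 5 up and 5 down of 28 (9 adjusted over the list alone), with RPL30 at 0.52 (SE 0.07) and RPL27 at -0.50 (SE 0.08). The gene of this list with the largest value, RPL37A (log2 3.63), had another probe called in the opposite direction.

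Few markers of other cell types were measured. Of 12 leukocyte genes 5 were measured, of which 3 rose and 1 fell (4 adjusted over the list alone), with the lysozyme gene LYZ at least 2.16-fold up to 6.23. Of 11 fibroblast genes 4 were measured, 1 up and 2 down (3 adjusted over the list alone). COL1A2, which the line itself expressed at 11.57 in triple negative cells, fell at least 93.8-fold, COL3A1 fell at least 7.02-fold, and COL1A1 rose at least 2.76-fold. Neuroendocrine genes numbered 0 up and 1 down of 3 measured (1 adjusted over the list alone). Endothelial genes numbered 1 up and 1 down of 2 (2 adjusted over the list alone), and Hedgehog genes 0 up and 1 down of 2 (1 adjusted over the list alone). Acinar genes were 1 up of 1 (1 adjusted over the list alone) and erythroid genes 2 up of 2 (2 adjusted over the list alone). These last 4 lists were too short for the list test.

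Other genes among the 10 largest rises were the lactate dehydrogenase subunit LDHB (at least 123-fold), the surface protein mesothelin, MSLN (at least 98.0-fold), the siderophore-binding protein LCN2 (at least 81.5-fold), the annexin ANXA3 (at least 68.0-fold) and the growth factor BMP4 (log2 7.22, SE 0.18). Other genes among the 10 largest falls were TXNIP, the thioredoxin-interacting protein (at least 150-fold), TM4SF18 (at least 69.2-fold), the regulator of G protein signalling RGS4 (log2 -7.20, SE 0.14), the acute-phase protease inhibitor SERPINA3 (log2 -6.75, SE 0.14) and the proteoglycan core SRGN (log2 -6.74, SE 0.09). Over all genes tested, 66.7% had all 4 arrays of a group above all 4 of the other where chance gives 2.86%. Limma's moderated test gave adjusted p-values from 6.61e-16 to 6.96e-13 for these 20 genes. The median, mean and test of the list differed in sign for the FOX family, sterol synthesis, hypoxia and glycolysis, immediate early, protease and invasion, and oxidative stress lists, none of which passed. Camera with a correlation estimated from the data called 0 of 29 lists (4 at an unadjusted p under 0.05, lowest adjusted p 0.0539). The count of genes changed at least 2-fold was 2400 with a normexp offset of 50, 1682 in the authors' value table and 2036 among genes detected on all 12 arrays.

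**Figure D2:**
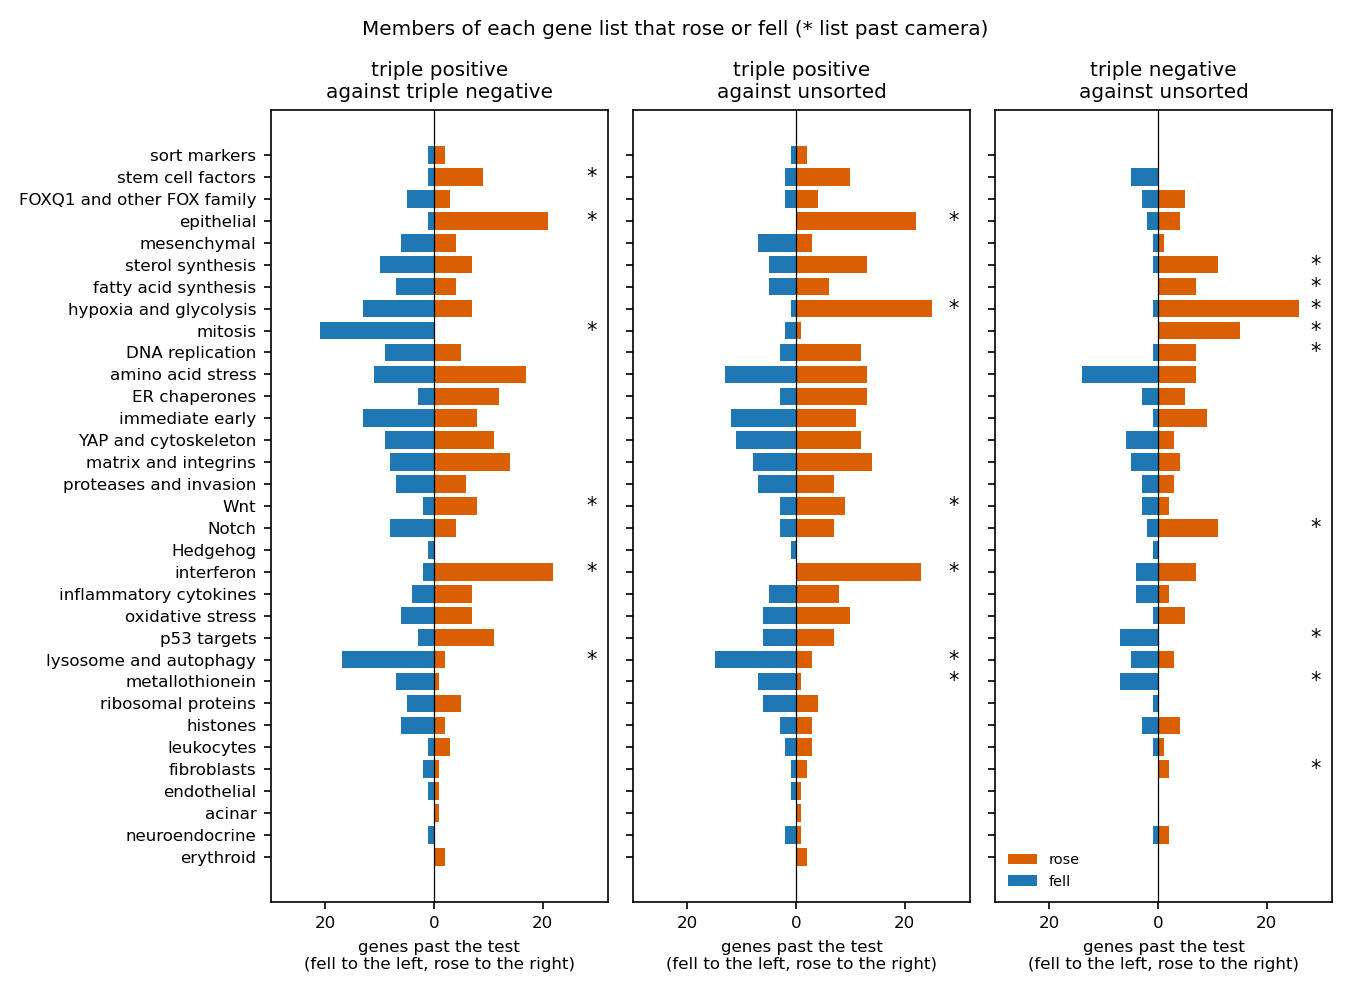
Number of genes of each list that rose (orange, to the right) or fell (blue, to the left) in the 3 comparisons, with an asterisk where camera called the list at the preset correlation (6, 6 and 9 lists; 0, 1 and 0 with an estimated correlation). Epithelial genes rose in triple positive cells against both other groups (21 and 22 of 23), and hypoxia and glycolysis genes rose against unsorted cells in both sorted groups (26 and 25 of 30).

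Triple positive against unsorted cells asks how the cells labelled as sorted positive differ from unsorted cells. Epithelial genes (22 of 23) and interferon-induced genes (23 of 28) rose here too, and the largest rises were those of IFI27 (log2 8.27, SE 0.12), SERPINE2 (log2 7.86, SE 0.18) and EPCAM. The EPCAM probe compared was above background on no unsorted array, so its log2 difference of 7.88 (SE 0.11) is one from background. Hypoxia and glycolysis genes, split against triple negative cells, rose here in 25 of 30. The protease inhibitor SERPINA3 (log2 -8.22, SE 0.14) and TM4SF1 (at least 227-fold) fell most. Of the 13313 genes, 9371 (70.4%) changed, 4426 upward and 4945 downward, with 3645 at least 2-fold (1944 upward, 1701 downward) and 208 at least 16-fold (149 upward). Both majorities again turned with scaling, to 4923 upward and 4389 downward after cyclic loess and to 1705 upward and 1996 downward at least 2-fold with 75th percentile scaling.

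The epithelial list had 22 genes up, none down and 1 not past (22 adjusted over the list alone; median log2 2.83, or 2.32 with genes at their bound, adjusted p = 6.61e-11), and kept its call with an estimated correlation (adjusted p = 0.048). RAB25, a small GTPase of epithelial vesicle transport, rose at least 40.9-fold, MAL2 at least 95.4-fold, CLDN7 at least 26.5-fold and CDH1 at least 24.9-fold. Interferon-induced genes were 23 up, 0 down and 5 not past (24 adjusted over the list alone; median log2 1.71, adjusted p = 1.43e-08; adjusted p = 0.265 with an estimated correlation), with the antiviral membrane protein BST2 up by 5.79 (SE 0.13) and IFI6 by 4.92 (SE 0.11). On unsorted d the mean of this list differed by -0.32 from that of unsorted a to c. Hypoxia and glycolysis genes were 25 up, 1 down and 4 not past (26 adjusted over the list alone; median log2 1.08, adjusted p = 5.46e-07; adjusted p = 0.265 with an estimated correlation). ALDOC rose by 4.72 (SE 0.12), BNIP3 by 4.68 (SE 0.10) and the glucose transporter SLC2A1 by 3.43 (SE 0.12). On triple positive d the mean of this list differed by -0.29 from that of a to c.

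Wnt genes were 9 up and 3 down of 12 (12 adjusted over the list alone; median log2 1.08, or 0.88 with genes at their bound, adjusted p = 0.0324; adjusted p = 0.265 with an estimated correlation), with DKK1 up by 4.12 (SE 0.15) and CCND1 by 3.08 (SE 0.11). Cyclic loess ended this call (adjusted p = 0.0654), with a mean log2 difference of 1.29 against 1.24 in the main fit. Lysosomal and autophagy genes were 3 up, 15 down and 4 not past of 22 (18 adjusted over the list alone; median log2 -0.78, or -0.71 with genes at their bound, adjusted p = 0.0308; adjusted p = 0.828 with an estimated correlation). The lysosomal proteases CTSB and CTSD fell by 1.63 (SE 0.12) and 1.43 (SE 0.11). The list lost its call without triple positive d (adjusted p = 0.0523), with a mean difference of -0.57 against -0.61 over all arrays. On unsorted d the mean of this list differed by -0.37 from that of unsorted a to c. The difference of the groups was -0.66 over the a to c arrays and -0.45 between the d arrays. Metallothionein genes were 1 up and 7 down of 8 (8 adjusted over the list alone; median log2 -1.07, adjusted p = 0.0243; adjusted p = 0.327 with an estimated correlation), with MT1X, MT1G and MT1M down (log2 -2.21, SE 0.09, -2.62, SE 0.15, and at least 21-fold) and MT1F up at least 11.7-fold. Stem cell factors were 10 up, 2 down and 2 not past of 14 (12 adjusted over the list alone) without a call for the list (adjusted p = 0.0624). The list passed with the other detection filters (adjusted p = 0.0256 with none, 0.0456 with the looser and 0.0352 with the stricter one) and with every detected probe tested (0.0245). It also passed without unsorted a and with the replicate letter as a block on the 8 arrays (both 0.0469). Mesenchymal genes were 3 up and 7 down of 10 (10 adjusted over the list alone, adjusted p = 0.156), with a mean log2 difference of -1.63. By camera this list passed downward among genes detected on all 12 arrays (mean -2.95, adjusted p = 0.00557). It also passed with every detected probe tested (mean -1.9, adjusted p = 0.03).

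Mitosis genes showed no common direction against unsorted cells, with 1 up, 2 down and 31 not past of 34 (0 adjusted over the list alone; median log2 -0.05, adjusted p = 0.968). The a to c arrays differed by 0.08 in the list mean and the d arrays, which stood apart in both groups, by -0.48. The spindle checkpoint gene MAD2L1 rose by 1.34 (SE 0.41) and CENPF and KIF11 fell by 1.10 (SE 0.38) and 1.06 (SE 0.42). CENPF lost its call without triple positive b (adjusted p = 0.0591) or c (0.054). KIF11 lost it without unsorted d (log2 -0.58, adjusted p = 0.103) or triple positive a (0.09), b (0.0914) or c (0.101), and also without background correction, after cyclic loess, in the authors' values, without a detection filter and in the fit on 8 arrays (0.0502 to 0.0855). DNA replication genes were 12 up, 3 down and 19 not past of 34 (14 adjusted over the list alone; median log2 0.47, adjusted p = 0.393; adjusted p = 0.987 with an estimated correlation). At the preset correlation the list passed without unsorted d (mean log2 difference 0.92, adjusted p = 0.003), whose mean of 8.92 lay above the 7.19 to 7.27 of unsorted a to c. The licensing factor CDT1 rose by 2.32 (SE 0.43) and the thymidine kinase TK1 by 2.42 (SE 0.49).

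Sterol synthesis genes were 13 up and 5 down of 24 (18 adjusted over the list alone), fatty acid synthesis genes 6 up and 5 down of 14 (11 adjusted over the list alone), and Notch genes 7 up and 3 down of 15 (10 adjusted over the list alone). ER chaperone genes were 13 up and 3 down of 18 (17 adjusted over the list alone). None of these lists passed in the main fit. With the replicate letter as a block the ER chaperone list did, its adjusted p moving from 0.0864 to 0.0469. It also passed without a detection filter (0.0141) and with d left out of each group (0.0417). The sterol synthesis list passed without a detection filter (adjusted p = 0.00803), among genes detected on all 12 arrays (0.0457) and with every detected probe tested (0.0232). The fatty acid synthase FASN rose by 1.27 (SE 0.11), the Notch targets HEYL and HES4 at least 6.67-fold and by 2.50 (SE 0.12), and the chaperone HSP90B1 by 1.32 (SE 0.09). Inflammatory cytokine genes were 8 up and 5 down of 13 (13 adjusted over the list alone), with the chemokine CXCL5 down at least 9.96-fold and CXCL2 at least 4.61-fold. Of the 10 genes with the largest rises, RAC2, a small GTPase, and CRIP1 were not among those against triple negative cells. RAC2 was at least 89.2-fold higher than in unsorted cells, and CRIP1 rose by 6.94 (SE 0.12). TP63, the p53 family factor of basal epithelium, took a place among the 10 largest falls (at least 78.9-fold). S100A4, a calcium-binding protein among the fibroblast markers, rose by 0.22 (SE 0.07, adjusted p = 0.0116) and was at -0.03 with 75th percentile scaling.

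Limma's adjusted p-values for the 20 genes with the largest differences from unsorted cells ran from 6.71e-16 to 6.76e-13, and the arrays of the groups did not overlap for 60.4% of all genes where chance gives 2.86%. The median, mean and test of the list differed in sign for the FOX family, amino acid stress, immediate early, protease and invasion, fibroblast and neuroendocrine lists, none of which passed. Camera with an estimated correlation called 1 of 29 lists, and the 2-fold count was 2357 with an offset of 50, 1609 in the authors' value table and 1979 among genes detected on all 12 arrays.

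The comparisons of triple positive cells with both other groups called 7530 genes in the same direction, 3578 higher and 3952 lower in triple positive cells, and 190 in opposite directions. Among the 7530 were 2723 genes that changed at least 2-fold in both and 176 that changed at least 16-fold. EPCAM, FOXQ1, CDH1, IFI27, DKK1 and BNIP3 were higher in both and VIM, ALDH1A1, TM4SF1 and CBS lower in both. Both comparisons use the same triple positive arrays, so their log2 differences correlate even without an effect. Independent lists of the observed lengths would share 3264 genes. With the triple positive arrays split so that each comparison used other arrays, 6294 to 6418 genes were shared over 6 splits. Across genes, which are not independent replicates, the log2 differences of the comparisons correlated at r = 0.912 (0.888 to 0.904 with split arrays, a median of 0.5 in 50 simulations without effects), and their covariance was 1.364 against 0.0121 simulated.

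Triple negative against unsorted cells asks how cells sorted as negative for the 3 surface proteins differ from the unsorted culture, which was grown in the same serum-containing medium. The CD44 probe compared did not differ (log2 -0.07, SE 0.09, adjusted p = 0.579), while a dimmer CD44 probe was lower in triple negative cells (log2 -0.80, adjusted p = 0.00034 over all probes). The PROM1 and EPCAM probes compared were at background on all arrays of both groups and show no difference or lack of one, and another EPCAM probe was detected on 1 unsorted array. Hypoxia and glycolysis genes rose in triple negative cells in 26 of 30, led by the glucose transporter SLC2A3 (log2 6.06, SE 0.21), and metallothionein genes fell in 7 of 8. Of the 13313 genes, 4540 (34.1%) changed, 2273 upward and 2267 downward, with 649 at least 2-fold (348 upward, 301 downward) and 12 at least 16-fold (6 upward).

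The hypoxia and glycolysis list was 26 up, 1 down and 3 not past (27 adjusted over the list alone; median log2 1.17, adjusted p = 4.64e-19; adjusted p = 0.0618 with an estimated correlation). PFKFB4, which sets the level of a glycolytic activator, rose by 3.63 (SE 0.10), STC1 by 2.11 (SE 0.11), the enolase ENO2 by 2.34 (SE 0.14) and the phosphofructokinase PFKP by 1.70 (SE 0.09). Notch genes were 11 up, 2 down and 2 not past of 15 (13 adjusted over the list alone; median log2 0.74, adjusted p = 4.41e-05; adjusted p = 0.071 with an estimated correlation). The ligand JAG1 rose by 3.96 (SE 0.10) and the targets HES4, HES1 and NRARP by 2.93 (SE 0.12), 1.52 (SE 0.12) and 0.91 (SE 0.08). Sterol synthesis genes were 11 up, 1 down and 12 not past of 24 (13 adjusted over the list alone; median log2 0.24, adjusted p = 0.0025; adjusted p = 0.083 with an estimated correlation), with HMGCS1, an early enzyme of cholesterol synthesis, up by 1.55 (SE 0.10) and the LDL receptor by 0.86 (SE 0.11). Fatty acid synthesis genes were 7 up, 0 down and 7 not past of 14 (8 adjusted over the list alone; median log2 0.35, adjusted p = 0.00354; adjusted p = 0.249 with an estimated correlation), with FASN up by 0.98 (SE 0.11) and the desaturase FADS1 by 1.06 (SE 0.13). Unsorted d differed by -0.24 from unsorted a to c in the mean of this list.

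Metallothionein genes were 0 up, 7 down and 1 not past of 8 (7 adjusted over the list alone; median log2 -0.65, adjusted p = 2.05e-05; adjusted p = 0.071 with an estimated correlation), with MT1G down by a log2 difference of -2.19 (SE 0.15), MT1X by -1.37 (SE 0.09) and MT2A by -0.74 (SE 0.07). Here as well unsorted d differed by -0.24 from unsorted a to c in the list mean. Genes induced by p53 were 0 up, 7 down and 10 not past of 17 (8 adjusted over the list alone; median log2 -0.42, or -0.29 with genes at their bound, adjusted p = 0.0025; adjusted p = 0.402 with an estimated correlation). TP53I3, an oxidoreductase, fell by 1.41 (SE 0.15), and BTG2, which restrains proliferation, by 1.03 (SE 0.19). The fibroblast list, 2 up and 2 not past of 4 measured (2 adjusted over the list alone; median log2 0.85, adjusted p = 0.00354; adjusted p = 0.071 with an estimated correlation), rested on the collagens COL1A2, at 10.11 in unsorted and 11.57 in triple negative cells, and COL3A1, at 4.61 and 7.83.

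Cell cycle lists passed camera upward in triple negative cells at the preset correlation but not at the estimated one, and unsorted d stood apart in them. The estimated correlation was 0.968 for mitosis and 0.868 for DNA replication, and fry gave p = 0.0682 and 0.169. Mitosis genes were 15 up, 0 down and 19 not past of 34 (20 adjusted over the list alone; median log2 1.23, adjusted p = 4.41e-05; adjusted p = 0.832 with an estimated correlation), among them TOP2A at 1.61 (SE 0.45) and KIF11 at 1.42 (SE 0.42). KIF11 lost its call without unsorted a (adjusted p = 0.0501), b (0.062) or c (0.0592). DNA replication genes were 7 up, 1 down and 26 not past of 34 (6 adjusted over the list alone; median log2 0.70, adjusted p = 0.00354; adjusted p = 0.832 with an estimated correlation), with GINS4 up by 2.53 (SE 0.30) and the DNA ligase LIG1 by 1.18 (SE 0.27). On the a to c arrays the means of the mitosis and DNA replication lists were higher in triple negative cells by 1.70 and 1.11, whereas on the d arrays the differences were -0.46 and -0.59. ID2 and ID3, inhibitors of basic helix-loop-helix factors, rose by 4.04 (SE 0.78) and 3.66 (SE 0.65), with unsorted d 4.61 and 3.77 above the median of unsorted a to c. Without unsorted d their differences were 5.18 and 4.59.

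The other genes with the largest rises included SNAP25, a protein of vesicle fusion in neurons (at least 18.8-fold), the stress-induced cytokine GDF15 (at least 15.4-fold), the aldehyde dehydrogenase ALDH3A1 (at least 12.8-fold), the thrombin receptor family member F2RL2 (at least 10.8-fold) and TPD52L1 (log2 4.11, SE 0.15). The 10 largest falls included those of the tight junction gene CLDN11 (at least 36.5-fold) and of homeobox genes of the HOXB cluster, HOXB8 (log2 -5.36, SE 0.08), HOXB5 (log2 -4.10, SE 0.12) and HOXB7 (at least 6.96-fold). In triple positive cells HOXB8, HOXB5 and HOXB7 lay at 11.03, 10.14 and 10.65, against 11.10, 9.61 and 7.92 in unsorted and 5.74, 5.50 and 4.48 in triple negative cells. STAMBPL1 (at least 14.3-fold), CCM2L (at least 11.6-fold), PHLDB2 (at least 11.4-fold), BRINP3 (at least 8.09-fold), the desmosomal cadherin DSG2 (at least 6.72-fold) and the smooth muscle actin ACTA2 (log2 -3.48, SE 0.19) were the others.

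Among lists that did not pass, epithelial genes were 4 up and 2 down of 23 (5 adjusted over the list alone), with the mucin MUC1 and the keratin KRT19 up (log2 2.68, SE 0.20, and 1.23, SE 0.11) and KRT8 down (log2 -1.62, SE 0.08). KRT18 (log2 -1.32) and the Wnt receptor FZD7 (log2 1.02) each had another probe called the other way. Stem cell factors were 0 up and 5 down of 14 (5 adjusted over the list alone), with BMI1 at -0.81 (SE 0.10) and ALDH1A3 at -0.74 (SE 0.09). Interferon-induced genes were 7 up and 4 down of 28 (11 adjusted over the list alone), with ISG15 up by 1.77 (SE 0.11). Amino acid stress genes were 7 up and 14 down of 38 (24 adjusted over the list alone, adjusted p = 0.0848; adjusted p = 0.832 with an estimated correlation), with the asparagine synthetase ASNS down by a log2 difference of -1.73 (SE 0.20). At the preset correlation that list passed without unsorted d (adjusted p = 0.00266), whose list mean differed by -0.55 from the mean of unsorted a to c. Inflammatory cytokine genes were 2 up and 4 down of 13 (6 adjusted over the list alone), with the chemokines CXCL1 and CXCL5 down (log2 -2.80, SE 0.19, and -3.32, SE 0.18).

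FOXQ1 was higher in triple negative than in unsorted cells by 0.51 (SE 0.15, adjusted p = 0.0204). This difference did not pass with an offset of 50 (log2 0.29, adjusted p = 0.0773), in the authors' value table (log2 0.18, adjusted p = 0.236), or without unsorted a (log2 0.43) or triple negative b (log2 0.48). For the 20 genes with the largest differences limma's adjusted p-values ran from 7.15e-14 to 0.00128, and 33.7% of all genes showed no overlap of the groups where chance gives 2.86%. The median, mean and test of the list differed in sign for the mesenchymal, matrix and integrin, and ribosomal protein lists. Camera with an estimated correlation called 0 of 29 lists (5 at an unadjusted p under 0.05, lowest adjusted p 0.0618). The 2-fold count was 1147 without background correction, 360 with an offset of 50, 226 in the authors' value table and 385 among genes detected on all 12 arrays.

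**Figure D3:**
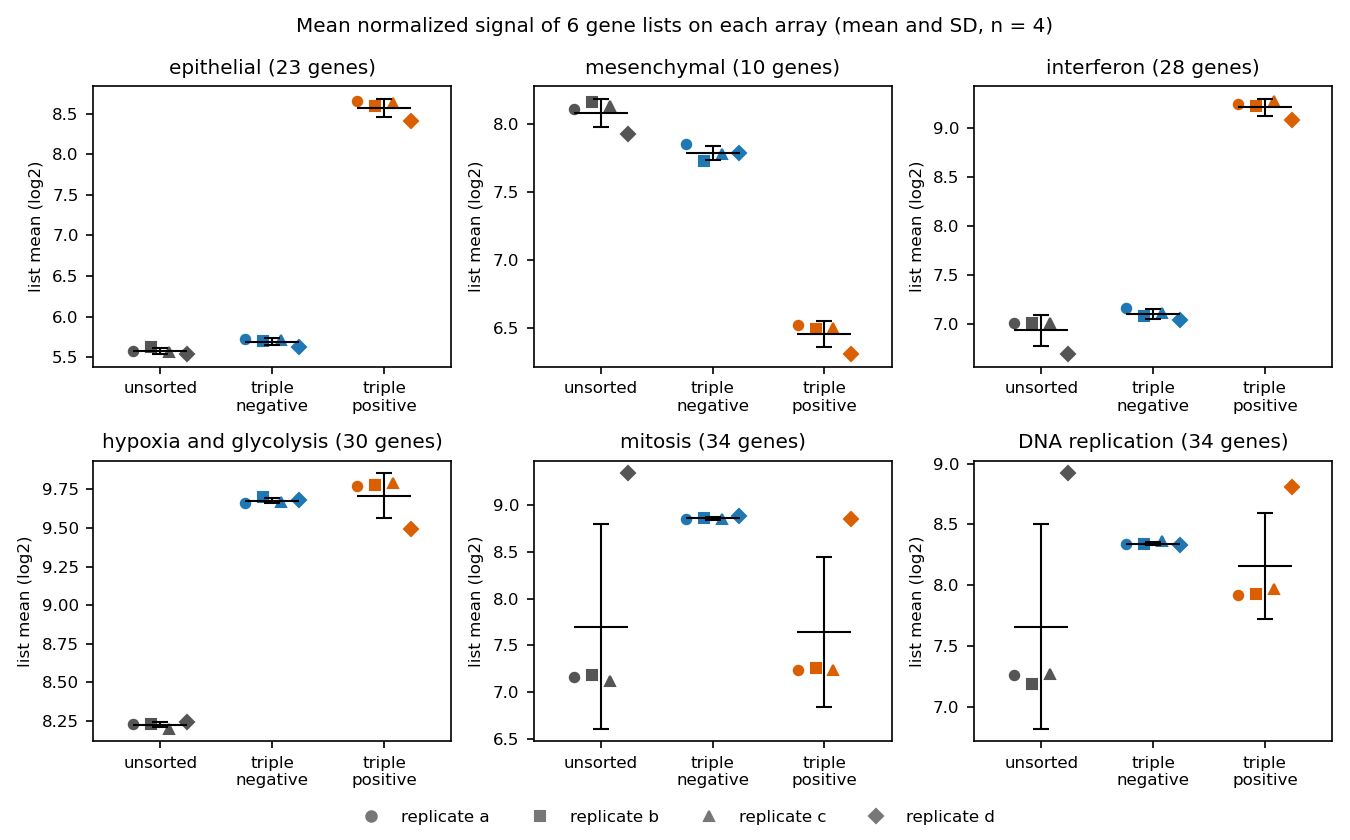
Mean normalized log2 signal of the genes of 6 lists on each array (points, shaped by replicate), with the mean and SD of each group (n = 4) and a separate vertical scale in each panel. Unsorted d (9.34) and triple positive d (8.85) lie above replicates a to c of their groups in the mitosis list (7.12 to 7.18 and 7.23 to 7.26), while the triple negative arrays lie between 8.85 and 8.88.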

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

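The tests for triple negative cells in the triple positive d sample and for a shared culture or batch of the d arrays were chosen late. Unsorted d and triple positive d had by then been seen to stand apart. In 115 of 768 sets of 4 arrays, 1 array lay so far from the nearest of the other 3 that the gap, as a share of the range of the 4, passed Dixon's critical value. This share is given in parentheses. Chance alone gives this in 1 of 20 sets, or 38.4 of 768. In 99 of the 115 the array was a d array. All values below come from single arrays and describe spread within a group.

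Unsorted d was the highest of the 4 unsorted arrays for ALDH1A1 (0.883), CDT1 (0.953), DKK1 (0.884), FOXM1 (0.846), ID2 (0.966), ID3 (0.972), MAD2L1 (0.957), PRIM1 (0.914), RGS4 (0.841), SLC2A1 (0.861), STAMBPL1 (0.851), TK1 (0.902) and TOP2A (0.924). It was the lowest for ACTA2 (0.920), ASNS (0.966), CCN2 (0.877), CD68 (0.859), CDKN1A (0.870), COL5A1 (0.851), CTH (0.944), CTSL (0.853), DDIT4 (0.892), EGR1 (0.948), FADS1 (0.837), FOXC1 (0.912), FOXK1 (0.877), FOXO3 (0.913), H2BC5 (0.891), IER3 (0.848), LIF (0.839), LSS (0.831), MT1M (0.948), MUC1 (0.872), SCG2 (0.908), SERPINA3 (0.908), SLC2A3 (0.873), TAGLN (0.931), TXNIP (0.940) and VLDLR (0.861). Among list means it was the highest for mitosis (0.970) and DNA replication (0.952). Its list means were the lowest for fatty acid synthesis (0.939), amino acid stress (0.944), immediate early (0.871), interferon (0.990), metallothionein (0.831) and ribosomal proteins (0.868). Other unsorted arrays stood apart for LCN2 (0.845, c lowest), PROM1 (0.932, b highest) and SNAP25 (0.901, a highest), all 3 at background there.

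Triple positive d was the highest of its group for ALDH3A1 (0.861), ATP6V0D1 (0.833), CENPF (0.830), CRELD2 (0.840), DNAJC3 (0.830), FOXM1 (0.860), GINS3 (0.952), GINS4 (0.965), ID3 (0.847), KIF11 (0.909), MAD2L1 (0.909), NR5A2 (0.914), PHLDB2 (0.964), TK1 (0.963), TOP2A (0.844) and VIM (0.838). It was the lowest for ACSS2 (0.956), ACTA2 (0.908), ADM (0.967), BNIP3 (0.911), CD24 (0.908), DUSP6 (0.889), ENO2 (0.846), GDF15 (0.840), HLA-DRA (0.863), HOXB7 (0.956), IFIT1 (0.915), LGALS1 (0.888), MSLN (0.908), MUC1 (0.910), OASL (0.868), PROM1 (0.851), RAC2 (0.836), RBPJ (0.975), SLC2A3 (0.867), STC2 (0.929) and TP53I3 (0.832). Its list means were the highest for mitosis (0.981) and DNA replication (0.941). They were the lowest for sort markers (0.929), stem cell factors (0.846), mesenchymal (0.859), hypoxia and glycolysis (0.915), amino acid stress (0.933), immediate early (0.885), matrix and integrins (0.894), inflammatory cytokines (0.899) and p53 targets (0.870). Other triple positive arrays stood apart for EPCAM (0.940, c highest), MT1G (0.899, c lowest) and HEYL (0.865, a lowest).

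Among triple negative arrays, d was the highest for ABCC2 (0.865), CD74 (0.843) and SERPINE2 (0.887). Array c was the highest for AXIN2 (0.907) and ENO2 (0.854) and the lowest for TM4SF1 (0.866). Array b was the highest for CRIM1 (0.864) and H4C8 (0.830) and the lowest for RPS14 (0.871). Array a was the highest for FOXA1 (0.964) and STC2 (0.837). Triple negative a was also the lowest in the mean of the stem cell factors (0.905) and in the 75th percentile of the raw signal (0.921). With 11 named genes of 224, the triple negative group had about the 11.2 that chance gives, while the unsorted group had 42 and the triple positive group 41.

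Chance as the source of the gene counts was tested by regrouping the 8 arrays of each comparison. The real grouping was the only 1 of the 35 splits that gave as many genes in triple positive against triple negative (9239), triple positive against unsorted (9371) and triple negative against unsorted cells (4540). The highest count of any other split was 0 in each, and 2395, 3275 and 3122 genes at an unadjusted p under 0.05 against 9554, 9667 and 5859 for the real grouping. A share of 1 of 35 is the smallest this test can give, so it argues against chance and does not exclude it. Every other split mixes both groups on each side, which widens the spread, so the counts of 0 add little. The test cannot tell a difference between the groups from one of cultures or batches that follow them. The splits that part the arrays of every letter also gave 0.

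Many genes were at background in 8 arrays and bright in the 4 triple positive arrays or the reverse. Normalization to a common distribution as the whole cause was not excluded by the criterion written beforehand, as the authors' values gave a 2-fold count of 1682 against 3659. Those values were set aside afterwards, since they too have a common distribution, and an added constant. With 75th percentile scaling the count was 3774 and after cyclic loess 3659, which argues against this cause. A candidate explanation is cells of another line in the triple positive arrays: of MTAP, CDKN2A and CDKN2B, neighbours on chromosome 9 that are commonly absent from the MiaPaCa-2 genome, 2 were above background on all 4 triple positive arrays and on none of the 8 others, and CDKN2B on 4 and on 1. Another CDKN2B probe was detected on the 4 triple positive arrays alone (6.29 ± 0.15), and a further one on no array. Neighbouring genes also shifted together, with an SD of window medians 1.69 times the highest of 100 shuffles of gene order, but triple negative against unsorted cells gave 1.46, so this test leaves open whether the chromosomes differ. That comparison was not free of such shifts, as every window of chromosome 7 had a negative median (-0.07 to -0.33). In triple positive against triple negative cells every window of chromosome 4 had a positive median (0.13 to 0.47) and every window of chromosome 5 a negative one (-0.02 to -0.64). These chromosomes were picked after the values were seen, and many others had windows of both signs. A minor subclone of the line that keeps these genes stays open too. A change of state in sphere medium stays open for other genes, but it would not bring back genes absent from the genome. Whether MTAP and CDKN2A are absent from the cells of the other arrays was not tested. LDHB, at background in unsorted cells, limits cells of its triple positive level to 0.817% of the unsorted signal.

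Unsorted d and triple positive d stood apart from replicates a to c of their groups, above all in mitosis and DNA replication genes. Lower array quality is argued against, as both arrays lay within the range of the other 10 in at least 2 of 3 measures (probes detected, median beads, share of the 100 brightest probes), though unsorted d had the fewest probes detected (15113) and triple positive d the lowest median of beads (21). Triple negative cells in the triple positive d sample were not excluded by the criterion set first. Of 301 genes that were highest in triple negative cells and at background on triple positive a to c, 31 (10.3%) were above background on d, where under 10% was asked for. By a criterion added after that was seen, triple negative cells are argued against. The 13 abundant genes among the 301 reached a median of -0.01% of the triple negative signal on d (upper quartile 0.06%), where 27 mitosis genes reached 81.6% (lower quartile 48.3%). Unsorted cells as the source were not tested. A shared culture or processing batch of the d arrays stays open, no biological explanation was tested, and the deviations of both arrays correlated across genes at 0.51 but those of triple negative d with either did not (0.006 and -0.011).

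Triple negative against unsorted cells gave 4540 changed genes, and 5713 without unsorted d. On the a to c arrays the mitosis list was higher in triple negative cells by 1.70, and on the d arrays by -0.46, so the direction of this list depended on the replicate. The triple negative arrays may have been handled as the d arrays of the other groups were, and across genes the difference between triple negative cells and unsorted a to c correlated at 0.198 with that between triple positive d and triple positive a to c, between the 0.3 and 0.1 that would have argued for and against it. Its correlation of 0.509 with the difference between unsorted d and unsorted a to c is raised by the unsorted a to c arrays that both use. Density and growth phase of the cultures are not given in the sources used here, and stay open.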

How the results depend on the processing

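Leaving out the d arrays together, unsorted d with triple positive d, and the replicate block on 8 arrays were chosen after seeing the data. The gene counts of the 3 comparisons and of genes shared by both triple positive comparisons stayed within 1.5 times their reported values under each alternative, as did FOXQ1 in direction and call in triple positive cells. Counts at least 2-fold moved. With a normexp offset of 50 they were 2400, 2357 and 360 (triple positive against triple negative, triple positive against unsorted, triple negative against unsorted; reported 3659, 3645 and 649), in the authors' values 1682, 1609 and 226, and among genes detected on all 12 arrays 2036, 1979 and 385. Larger constants shrink the differences of dim genes and the stricter filter tests fewer genes. Without background correction triple negative against unsorted gave 1147. Camera with an estimated correlation called 0, 1 and 0 lists in place of 6, 6 and 9. FOXQ1 in triple negative against unsorted cells did not pass with an offset of 50 (0.29, adjusted p = 0.0773) or in the authors' table (0.18, adjusted p = 0.236). The cause was not tested. S100A4 in triple positive against unsorted cells went from 0.22 to -0.03 with 75th percentile scaling, which moved the median of all genes from -0.056 to -0.165 (against triple negative from -0.067 to -0.166). With 1 array left out at a time, FOXQ1 ran from 5.58 to 5.79, 6.07 to 6.30 and 0.43 to 0.60, the last without a call when unsorted a or triple negative b was out. Lists called ran from 5 to 6, 5 to 7 and 9 to 10, and 2-fold counts from 3608 to 3769, 3591 to 3838 and 594 to 862. Changed genes ran from 8756 to 9708, 8969 to 9726 and 3760 to 5713, and shared genes from 7153 to 7727. Without unsorted d and triple positive d, 10059, 10008 and 6769 genes changed. The replicate block on 12 arrays gave 9452, 9524 and 4876 changed genes and 0.51 for FOXQ1 in triple negative against unsorted cells, and on the 8 arrays of triple positive and unsorted cells 9523. The block on 8 arrays brought the stem cell and ER chaperone lists past the test (both adjusted p = 0.0469), and a replicate block changed no other call of a list or named gene. Of the genes called on 8 arrays 9115 were among the 9371 reported. For the 356 named gene differences, 14 calls were lost with the direction kept over all other alternatives and 21 with 1 array left out, mostly of CENPF, FOXM1, KIF11 and SCG2. S100A4 lost its call as well as its direction. Of the list calls, 20 were lost with an estimated correlation, 6 under other alternatives and 6 with 1 array left out, and 29 and 4 were gained under other alternatives and with 1 array left out. Genes missing under the stricter filter have no value there, the slide block was not run, and differences from a group below 4.98 to 5.22 log2 units are bounds or of uncertain size.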

Other observations

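Several neighbouring genes on the short arm of chromosome 9 were on in triple positive cells and off elsewhere. They were chosen after their values were seen, except MTAP, CDKN2A and CDKN2B. MTAP, an enzyme of methionine salvage, lay at 10.26 ± 0.08 (SD, n = 4) in triple positive cells and at 4.60 ± 0.14 in triple negative and 4.55 ± 0.13 in unsorted cells. KLHL9, an adaptor of a ubiquitin ligase, lay at 8.34 ± 0.07 against 4.43 ± 0.09 and 4.41 ± 0.08. CDKN2A and CDKN2B, inhibitors of the cyclin-dependent kinases of G1, reached 6.16 ± 0.20 and 5.88 ± 0.40 against 4.47 ± 0.23 and 4.99 ± 0.18 in triple negative and 4.38 ± 0.07 and 4.64 ± 0.21 in unsorted cells. FOCAD (6.50) and IFNE (5.61) were detected on the 4 triple positive arrays alone. HACD4, which lies between FOCAD and KLHL9, was detected on all 12 arrays (7.52, 7.21 and 7.01 in unsorted, triple negative and triple positive cells). So was RPS6, farther out (13.97, 13.91 and 13.95). Most other probes of the region, those of the interferon cluster, were at background on every array.

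Genes along the long arm of chromosome 8 were higher together in triple positive cells. In 4 consecutive windows of 40 tested genes each, chosen after the values were seen, the median log2 differences from triple negative cells were 0.90, 0.88, 0.80 and 0.95, and those from unsorted cells 0.96, 0.83, 0.76 and 1.11. Those of triple negative from unsorted cells were 0.00, -0.06, -0.05 and -0.06. Of the 40 genes of each window, 29, 32, 30 and 28 were called higher than in triple negative cells. The lowest medians against triple negative cells lay on chromosome 16 from CDH1 to DHX38 (-0.80 from triple negative, -0.66 from unsorted cells), on chromosome 12 from SLC6A12 to CHD4 (-0.73 and -0.50) and on chromosome 3 from GPR160 to ABCF3 (-0.69 and -0.68). Against unsorted cells the lowest lay on chromosome 16 from C16orf87 to RSPRY1 (-0.88, and -0.64 from triple negative cells). CDH1 itself rose (log2 5.46, SE 0.10, against triple negative cells). Over the 284 windows the SD of the medians was 0.289, 0.303 and 0.101 in triple positive against triple negative, triple positive against unsorted and triple negative against unsorted cells, and at most 0.171, 0.172 and 0.069 in 100 shuffles of gene order. Chromosome and gene order came from the reference gene table (GRCh38.p14), whose coordinates were not used otherwise.

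For 2278 probes with a signal above 500, the SD of the difference between replicate arrays was 0.108 to 0.136 log2 units for pairs without a d array, where the bead standard errors alone give 0.082 to 0.108. With the d arrays it reached 0.377.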
